A study of Mus musculus with 6 samples.

How the data were processed

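The series measured poly(A) RNA of RAW264.7 cells by RNA sequencing in 6 libraries, 3 without IL-4 (M0) and 3 with IL-4 (M2). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, poly(A) RNA was isolated from total RNA with magnetic beads and libraries were made with an Illumina kit of New England Biolabs. The submitters' processing notes name bcl2fastq, STAR 2.7.5a, HOMER 4.11.1, DESeq2 and the build mm10, without saying which step each served. The gene annotation, strand setting and treatment of multiply mapped reads are not given in the sources used here.

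Both deposited tables were used. Per the file headers, the first holds TPM values by the authors for 25124 genes in each of the 6 libraries, with 1 transcript model and its length per gene. The deposited TPM columns sum to between 550163 and 559556 per library, so they are not shares of the listed genes alone. The second holds 24421 genes with the authors' values per library, read here as log2-scale normalized values from their range, since the header of the deposited table does not name the transform. Per the file headers it also holds the authors' log2 fold change, p-value and adjusted p-value for M0 against M2. That log2 fold change is positive where M2 is higher, as checked on the columns per library. Of the gene symbols, 23553 are in both tables, and 804 of the other 868 in the comparison table are older names of genes in the TPM table.

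The design, the rule for named genes, the 31 lists and the alternatives given first below were set before the data were examined. The design was a count model if counts were deposited, and otherwise limma on log2(TPM + 1). Neither table holds counts as deposited by the authors, so the second was used. Genes with a TPM of at least 1 in at least 3 libraries were kept, 11202 in all, and fitted with limma 3.58.1 in R 4.3.3 by group alone, with a trend of the variance on the mean and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and at least 2-fold where its log2 fold change on log2(TPM + 1) was also at least 1 in size. Means and SDs in the text are of TPM over 3 libraries, and folds are ratios of those means. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and plots.

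TPM keeps no depth by itself, but TPM multiplied by model length came in whole multiples of 1 step per library. In each library 100.0% of the values fine enough to tell lay within 0.1 read of a whole number, where chance gives 20.0%. The reads recovered in this way are given per library with the results. They served for the reads behind a value and for alternatives. The 10 most abundant genes held 5.24% to 5.97% of the TPM. No pair of libraries was a duplicate: within groups, the chi-square per degree of freedom of recovered reads was between 2.18 and 19.6. Each same-group pair of libraries correlated at 0.991 or more on log2(TPM + 1), and pairs across groups at 0.975 or less.

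The fit was tested on simulated reads for M2 against M0 over 11151 genes, with 200 of them changed. It recovered 100.0% of genes at 0.25 times, 94.5% at 0.5 times, 51.0% at 1.3 times, 98.0% at 2 times and 99.5% at 4 times the M0 level, and 6.35% of its calls were false. The simulation had a single dispersion, no gene length trend and far fewer changed genes than the 4899 called in the data. These rates need not hold for the data. In the same test camera called the 1 list that had been raised and 0 of 24 random lists. The simulated genes varied independently, so this cannot show how camera behaves where the genes of a list vary together.

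The rule for named genes took the 10 largest rises and 10 largest falls among genes that passed, with non-overlapping groups and a log2 mean CPM of at least 3, leaving out predicted, Rik, microRNA and small nucleolar RNA genes. It also took 14 markers whatever their result, and up to 4 members of each list with the lowest adjusted p as examples. The 31 lists were alternative activation, IL-4 receptor and STAT6 pathway, classical activation, interferon-stimulated genes, antigen presentation, glycolysis, TCA cycle, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, lipid handling, arginine and polyamine metabolism, clock, cell cycle, lysosome, osteoclast, NRF2, unfolded protein response and ATF4, hypoxia, immediate early genes, macrophage identity, phagocytic receptors, adhesion and matrix, cytokine receptors, ribosomal proteins, and markers of 6 groups of other cell types. Lists with at least 5 tested members were tested with camera (two-sided, preset inter-gene correlation of 0.01, Benjamini-Hochberg over 25 lists), and counts of members are given over all genes tested and adjusted over the list alone. Lists of ribosome biogenesis genes (40) and of SMAD targets and feedback genes (10) were added after the comparison was seen.

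The alternatives set with the design were a pseudocount of 0.1, no filter, a filter at 5 CPM of recovered reads in at least 3 libraries, limma-voom on recovered reads, the replicate number as a block, leaving out each library in turn, camera with an estimated correlation, and fry. Chosen after seeing the data were median-ratio, upper-quartile and quantile scaling of TPM, removal of the trend on gene length from each library (loess, span 0.3), the authors' log2-scale values, protein-coding genes alone, and limma-voom with the block, without M2 replicate 3 or with upper-quartile factors (median-ratio factors elsewhere). Count models set with the design were tried on the recovered reads after the other results were seen, in a separate trial whose values are not in the tables. Genes below the filter were left out of tests, and their reads are given where they are named.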

Results

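RAW264.7 is a mouse macrophage-like cell line. The cells of this series were a control line that had received Cas9 without a guide RNA, made beside a knockout of E4BP4, the protein that Nfil3 encodes. Cells were grown in medium with 25 mM glucose and 10% serum. They were left without cytokine (M0) or given IL-4 at 10 ng/ml to polarize them toward the M2 state of alternatively activated macrophages. RNA sequencing of poly(A) RNA, from 200 ng of total RNA each, gave 3 libraries per group. The files list 25124 genes in TPM, a measure of transcript abundance scaled for gene length and depth. Reads recovered from the TPM values came to 18110568, 18104946 and 15615639 for M0 replicates 1, 2 and 3, and 18344446, 18139902 and 19511192 for M2 replicates 1, 2 and 3. The library totals in the authors' file headers are 1.18 to 1.20 times as high. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. All 3 M0 libraries, and none of the M2 libraries, carry a re-analysis note in the labels, so any batch behind that note and IL-4 cannot be told apart.

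The study's single comparison asks which transcripts differ between IL-4-polarized and unpolarized cells. Arg1, the arginase that turns arginine into ornithine and urea, rose from 0.174 ± 0.0719 TPM in M0 to 15.3 ± 0.653 TPM in M2 (SD, n = 3 each), and Slc7a2, a transporter that imports arginine, rose 13.0-fold. Mrc1, the mannose receptor CD206, rose 13.8-fold and Socs1, a feedback inhibitor of cytokine receptor signalling, 42.8-fold. Tnf, an inflammatory cytokine gene, fell from 23.7 ± 1.00 TPM in M0 to 7.45 ± 0.687 TPM in M2, and Nlrp3, the inflammasome sensor, was 3.18-fold lower in M2. Of tested alternative activation markers 13 of 17 rose, and 13 of 17 hypoxia response genes, 16 of 27 glycolysis genes and 25 of 41 interferon-stimulated genes fell. Of all 11202 tested genes 2248 rose and 2651 fell. Camera called these lists with a preset inter-gene correlation, and 0 lists with an estimated one. Nfil3, whose product is E4BP4, rose from 30.1 ± 0.803 TPM in M0 to 52.1 ± 0.953 TPM in M2.

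With limma on log2(TPM + 1), 4899 of 11202 tested genes changed at an adjusted p under 0.05, of which 2248 rose and 2651 fell in M2. Of these, 275 changed at least 2-fold on that scale, 118 upward and 157 downward, and the scale understates the change of genes with low TPM. Every M2 library lay on the same side of every M0 library for 6264 genes (55.9%, where chance gives 10%). The groups separated on the first principal component, which held 70.3% of the variance, and the median log2 fold change over all tested genes was -0.03. The count at 2-fold moved with the processing: it was 472 with a pseudocount of 0.1, 477 with limma-voom on the recovered reads (495 with upper-quartile factors) and 89 on the authors' deposited log2-scale values. The balance of rises and falls also moved: 2638 rose and 2552 fell with median-ratio scaling, 2680 and 2679 with limma-voom, and 2650 and 2522 on the authors' values. M2 replicate 3 differed from both other M2 libraries in a trend with gene length, and without it 5694 genes changed (2869 rose, 2825 fell), 285 of them at least 2-fold.

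**Figure D1:**
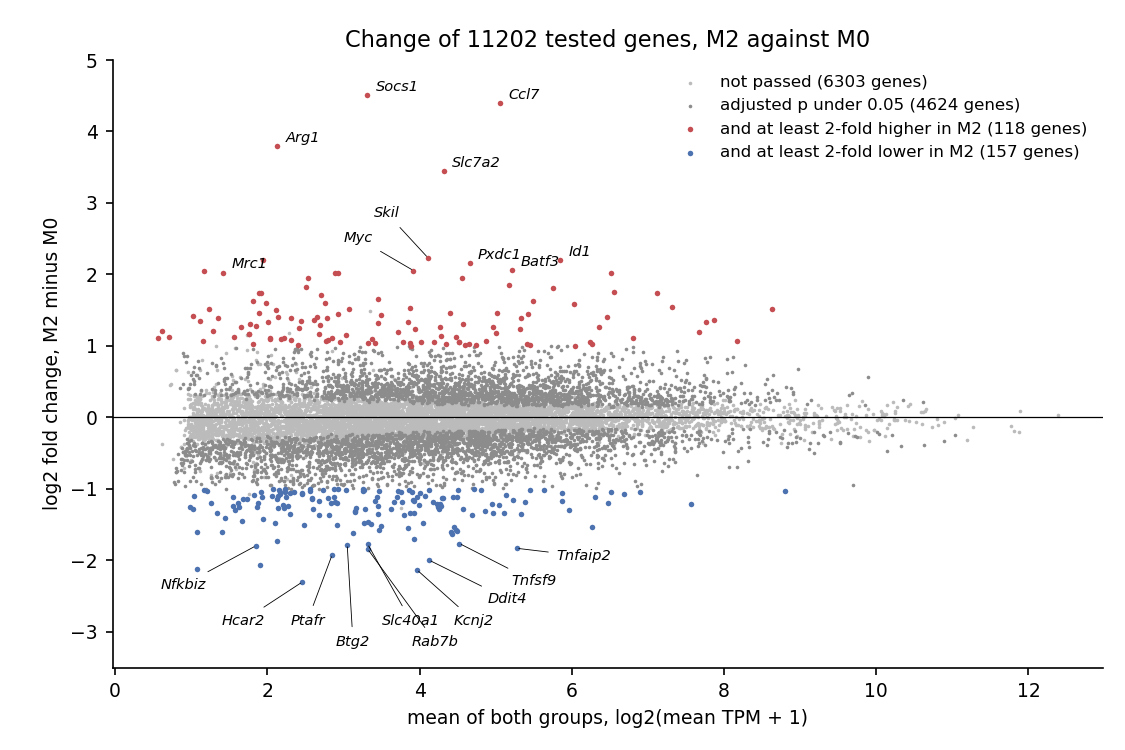
Each point is 1 of 11202 tested genes; the horizontal axis gives the mean over both groups as log2(mean TPM + 1), the vertical axis the log2 fold change of M2 (3 libraries) against M0 (3 libraries). Red points (118 genes) rose and blue points (157 genes) fell at least 2-fold at an adjusted p under 0.05, and the 10 largest rises and 10 largest falls under the rule for named genes are labelled.

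On log2(TPM + 1), which understates the change of genes with low TPM, the largest rises under the rule for named genes were those of Socs1 (log2 fold change 4.51, SE 0.092, adjusted p = 4.29e-08) and Ccl7, which encodes a monocyte-attracting chemokine (4.40, SE 0.12, adjusted p = 1.77e-07). Arg1 (3.80, SE 0.094, adjusted p = 1.26e-07) rested on 11 reads over the M0 libraries and 1075 over the M2 libraries. By the ratio of mean TPM Arg1 came first, at 87.9-fold against 42.8-fold for Socs1. Slc7a2 rose from 5.02 to 65.0 TPM. The next were Skil (6.95 to 36.5 TPM), which encodes a repressor of SMAD proteins, and Id1 (25.8 to 122 TPM), an inhibitor of basic helix-loop-helix factors. Pxdc1 rose 4.75-fold, the transcription factor genes Batf3 and Myc from 17.2 to 75.3 TPM and from 6.43 to 29.8 TPM, and Mrc1 from 0.321 to 4.43 TPM. The log2 fold changes of these last 6 genes lay between 2.03 and 2.23. By the rule, which required non-overlapping groups, each of the 10 genes was higher in 3 of 3 M2 libraries than in any M0 library.

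The largest falls under that rule, on the same scale, were those of Hcar2, the niacin receptor (log2 fold change -2.30, SE 0.085, adjusted p = 9.01e-07), and Kcnj2, an inward-rectifier potassium channel (-2.14, SE 0.11, adjusted p = 4.10e-06). Ddit4, an inhibitor of mTORC1 induced by low oxygen and stress, fell from 33.7 ± 1.65 TPM in M0 to 7.76 ± 1.41 TPM in M2 (SD, n = 3 each). Ptafr, the receptor of platelet-activating factor, was 4.82-fold lower, the small GTPase gene Rab7b 4.18-fold and Tnfaip2 3.68-fold. Nfkbiz, a nuclear regulator of NF-kappaB targets, went from 5.70 to 0.933 TPM, and by the ratio of mean TPM its fall of 6.11-fold came after that of Hcar2 (7.62-fold) and before that of Kcnj2 (4.88-fold). Btg2 was 4.15-fold lower, the iron exporter gene Slc40a1 3.97-fold and Tnfsf9, the ligand of 4-1BB, 3.61-fold. Log2 fold changes of the 10 genes ran from -2.30 to -1.77.

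On mm10, the build named in the submitters' processing notes, the transcript that the authors' file uses for Arg1 is NM_007482, chromosome 10, 24915207 to 24927470, minus strand. The Socs1 model is NM_009896, chromosome 16, 10783809 to 10785536, minus strand, and that of Ccl7 is NM_013654, chromosome 11, 82045712 to 82047523, plus strand. Slc7a2 is measured on NM_001044740, chromosome 8, 40862367 to 40922070, plus strand. The Hcar2 model is NM_030701, chromosome 5, 123863570 to 123865516, minus strand, and that of Kcnj2 is NM_008425, chromosome 11, 111066164 to 111076825, plus strand. Strand use in the counting is not given in the sources used here, so reads from overlapping genes cannot be assigned with certainty.

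Of the markers chosen in advance, Ccl24, a chemokine of alternative activation, rose from 1.69 ± 0.0608 TPM in M0 to 3.21 ± 0.624 TPM in M2 (SD, n = 3 each; adjusted p = 0.00297 by limma). Il4ra, the receptor subunit that binds IL-4, rose 1.95-fold, and Pparg, a lipid-sensing nuclear receptor, went from 0.426 to 1.58 TPM. Adgre1, which encodes the macrophage antigen F4/80, rose 2.23-fold. Stat6, the transcription factor downstream of the IL-4 receptor, fell slightly, from 65.5 ± 3.19 TPM in M0 to 52.2 ± 6.43 TPM in M2 (adjusted p = 0.0168). Its adjusted p was 0.0516 without M0 replicate 1 and 0.0644 without M0 replicate 2, within a range of 0.00146 to 0.0644 over 20 alternatives. Spi1, which encodes the macrophage factor PU.1, stood at 201 ± 8.58 TPM in M0 and 182 ± 10.7 TPM in M2 and did not pass (adjusted p = 0.0802). It passed without M2 replicate 3 (adjusted p = 0.0130) and with the replicate number as a block (adjusted p = 0.0446). In all it passed under 5 of 20 alternatives, within a range of 0.00456 to 0.306. The other 4 markers lay below the filter and were not tested. Retnla had 1 read over the 3 M0 libraries and 2 over the 3 M2 libraries. Chil3 had 0 and 5 reads, where a count of 0 allows up to 3, Irf4 73 and 70, and Nos2, the inducible nitric oxide synthase, 27 and 13.

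**Figure D2:**
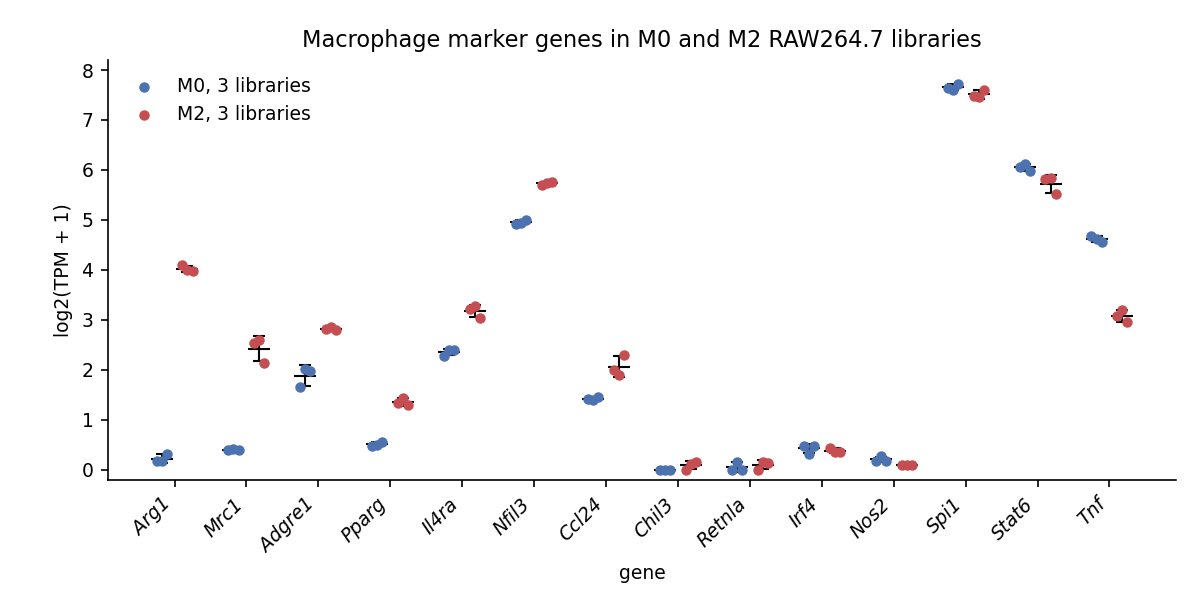
Points are single libraries (blue, 3 M0; red, 3 M2) of the 14 marker genes chosen in advance, on log2(TPM + 1), with bars for the group mean and SD; genes are ordered by their difference. Arg1 stands at 0.174 TPM in M0 and 15.3 TPM in M2, while Chil3, Retnla, Irf4 and Nos2 lie near 0 in both groups.

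Of 31 gene lists fixed in advance, 25 had at least 5 tested members, and camera with a preset inter-gene correlation of 0.01 called 8 of these 25 at an adjusted p under 0.05, 1 upward and 7 downward. With the correlation estimated from the 6 libraries it called 0 lists (2 at an unadjusted p under 0.05). At the preset correlation, splits of the 6 libraries that mix M0 and M2 on each side called up to 9 lists. Such splits keep part of the group difference, so this is not a rate of chance calls. Fry, which asks whether a list's genes move one way on balance without comparing them with other genes, called 15. In a trial of edgeR on the recovered reads, whose values are not in the tables used here, camera did not call antigen presentation or the lysosome. In that trial it called 4 lists that are not among the 8. The IL-4 receptor and STAT6 pathway and arginine and polyamine metabolism were called upward. Immediate early genes and chemokine and cytokine receptors were called downward. Over the 21 camera alternatives given here, the lowest adjusted p of these lists was 0.537, 0.246, 0.0485 and 0.152 in that order. Those alternatives thus did not share the trial's calls, apart from immediate early genes under 1 of them. Members named below only to complete a count of 5 or fewer were chosen after their values were seen.

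Alternative activation markers rose as a group. Of 17 tested members 13 rose and 3 fell (14 and 3 adjusted over the list alone), with a median log2 fold change of 0.85 (camera adjusted p = 1.60e-06; adjusted p = 0.283 with an estimated correlation, and 4.54e-07 to 0.283 over 21 camera alternatives). Besides Arg1, Slc7a2 and Mrc1, the lectin genes Mgl2 and Clec7a rose 4.13-fold and 4.14-fold, to 183 ± 9.55 and 45.6 ± 3.70 TPM (SD, n = 3). The 3 that fell were Il1r2, a decoy receptor of IL-1, Tgfb1 and the fibronectin gene Fn1. The 22 members below the filter together held 86 to 112 reads per M0 library and 169 to 207 per M2 library. Genes of the IL-4 receptor and STAT6 pathway went both ways: of 24 tested 9 rose and 9 fell (9 and 9 adjusted over the list alone), with a median of -0.03, a mean of 0.29 and an upward camera test that did not pass (adjusted p = 0.606). Jak2, a kinase of cytokine receptors, rose 2.89-fold next to Socs1 and Myc, and Ptpn6, the phosphatase SHP-1, fell from 263 to 149.6 TPM. Arginine and polyamine genes were split in the same way, with 9 that rose and 10 that fell among 23 tested (9 and 10 adjusted over the list alone; camera adjusted p = 0.333). Gatm, which uses arginine to make creatine precursors, rose from 133 to 306 TPM, and Smox, spermine oxidase, fell from 134 to 57.9 TPM.

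Genes of classical activation and inflammation fell in the main. Of 31 tested 7 rose and 19 fell (7 and 19 adjusted over the list alone), with a median log2 fold change of -0.37 (camera adjusted p = 0.0140; adjusted p = 0.481 with an estimated correlation, and 0.00860 to 0.481 over 21 camera alternatives). Besides Tnf and Nlrp3, Cd14, the co-receptor for lipopolysaccharide, fell from 637 ± 5.66 TPM in M0 to 310.4 ± 6.69 TPM in M2 (SD, n = 3 each). The chemokines Ccl2 and Ccl7, both attractants of monocytes, moved the other way, and Ccl2 rose from 232 to 667 TPM. Interferon-stimulated genes were lower, with 41 tested, of which 4 rose and 25 fell (5 and 26 adjusted over the list alone). Their median was -0.33 (camera adjusted p = 1.58e-04; adjusted p = 0.481 with an estimated correlation, and 5.29e-05 to 0.481 over 21 camera alternatives). The GTPase gene Ifi47 was 3.92-fold lower, Dhx58, of the RNA sensor family, 2.18-fold and Ifi203 1.76-fold, the RNA sensor gene Ddx58 fell from 9.08 to 4.63 TPM, and Irf7, Ifi204, Gbp3 and Ifit1 rose. Antigen presentation genes fell in smaller steps: of 21 tested 3 rose and 13 fell (3 and 14 adjusted over the list alone). Their median was -0.25 (camera adjusted p = 0.0159; adjusted p = 0.481 with an estimated correlation, and 0.00556 to 0.481 over 21 camera alternatives). The peptide transporter genes Tap1 and Tap2 were 1.64-fold and 1.57-fold lower, and H2-Q4 and H2-Q6, class I genes with near-identical copies between which reads may be shared, fell from 147 to 114 TPM and from 60.7 to 48.6 TPM. Ctss, Erap1 and Psmb10 rose. The 7 members below the filter, among them the class II genes H2-Aa, H2-Ab1 and H2-Eb1, went the other way. Together they held 28 to 43 reads per M0 library and 61 to 86 per M2 library. The antigen presentation call ended without the filter on low values (adjusted p = 0.162) and on the authors' deposited log2-scale values (adjusted p = 0.0532). It also ended with limma-voom and upper-quartile factors (adjusted p = 0.0528). With M0 replicates 1, 2 and 3 and then M2 replicates 1, 2 and 3 left out in turn, 1, 2, 1, 2, 1 and 4 interferon-stimulated genes rose, and 1, 2, 0, 3, 3 and 3 antigen presentation genes.

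Hypoxia response genes fell without exception among those that passed: of 17 tested 0 rose and 13 fell (0 and 14 adjusted over the list alone), with a median log2 fold change of -0.50 (camera adjusted p = 1.17e-06; adjusted p = 0.283 with an estimated correlation, and 1.55e-08 to 0.283 over 21 camera alternatives). Ndrg1 fell from 130.3 ± 0.919 TPM in M0 to 44.4 ± 3.62 TPM in M2 (SD, n = 3 each), Bnip3, a mitophagy receptor, from 84.3 to 46.9 TPM and Slc2a1, the glucose transporter GLUT1, was 1.92-fold lower. Of 27 glycolysis genes 4 rose and 16 fell (4 and 18 adjusted over the list alone). Their median was -0.25 (camera adjusted p = 0.00238; adjusted p = 0.593 with an estimated correlation, and 1.13e-04 to 0.593 over 21 camera alternatives). Enolase 2 (Eno2) was 2.61-fold lower and the phosphofructokinase gene Pfkp fell from 112 to 55.9 TPM. Slc16a1, the lactate transporter MCT1, rose 2.02-fold, and Pfkfb4, Pfkfb3 and Slc2a3 also rose. Targets of the unfolded protein response and of ATF4 fell more often than they rose. Among 31 tested, 2 rose and 13 fell (2 and 13 adjusted over the list alone), while 16 did not pass. Their median was -0.07 (camera adjusted p = 0.0389; adjusted p = 0.619 with an estimated correlation, and 0.00860 to 0.619 over 21 camera alternatives). Herpud1 was 2.39-fold lower, Chac1 2.52-fold, Trib3 2.04-fold and Ppp1r15a 2.02-fold, while Atf3 and Dnajc3 rose. That list did not pass without M2 replicate 1 (adjusted p = 0.0974) or with limma-voom (adjusted p = 0.0964). Lysosome genes were the weakest call, with 6 that rose and 18 that fell (6 and 18 adjusted over the list alone) among 39 tested. Their median was -0.17 (camera adjusted p = 0.0468; adjusted p = 0.697 with an estimated correlation, and 0.0107 to 0.697 over 21 camera alternatives). Sqstm1, the autophagy receptor p62, fell from 193 to 121 TPM, and Atp6v1b2, a proton pump subunit, was 1.41-fold higher. The lysosome list did not pass without M0 replicate 1 (adjusted p = 0.105), M2 replicate 1 (0.0581) or M2 replicate 2 (0.0538). With M0 replicates 1, 2 and 3 and then M2 replicates 1, 2 and 3 left out in turn, 2, 3, 2, 1, 2 and 4 glycolysis genes rose, and 1, 1, 1, 1, 1 and 3 genes of the unfolded protein response list.

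**Figure D3:**
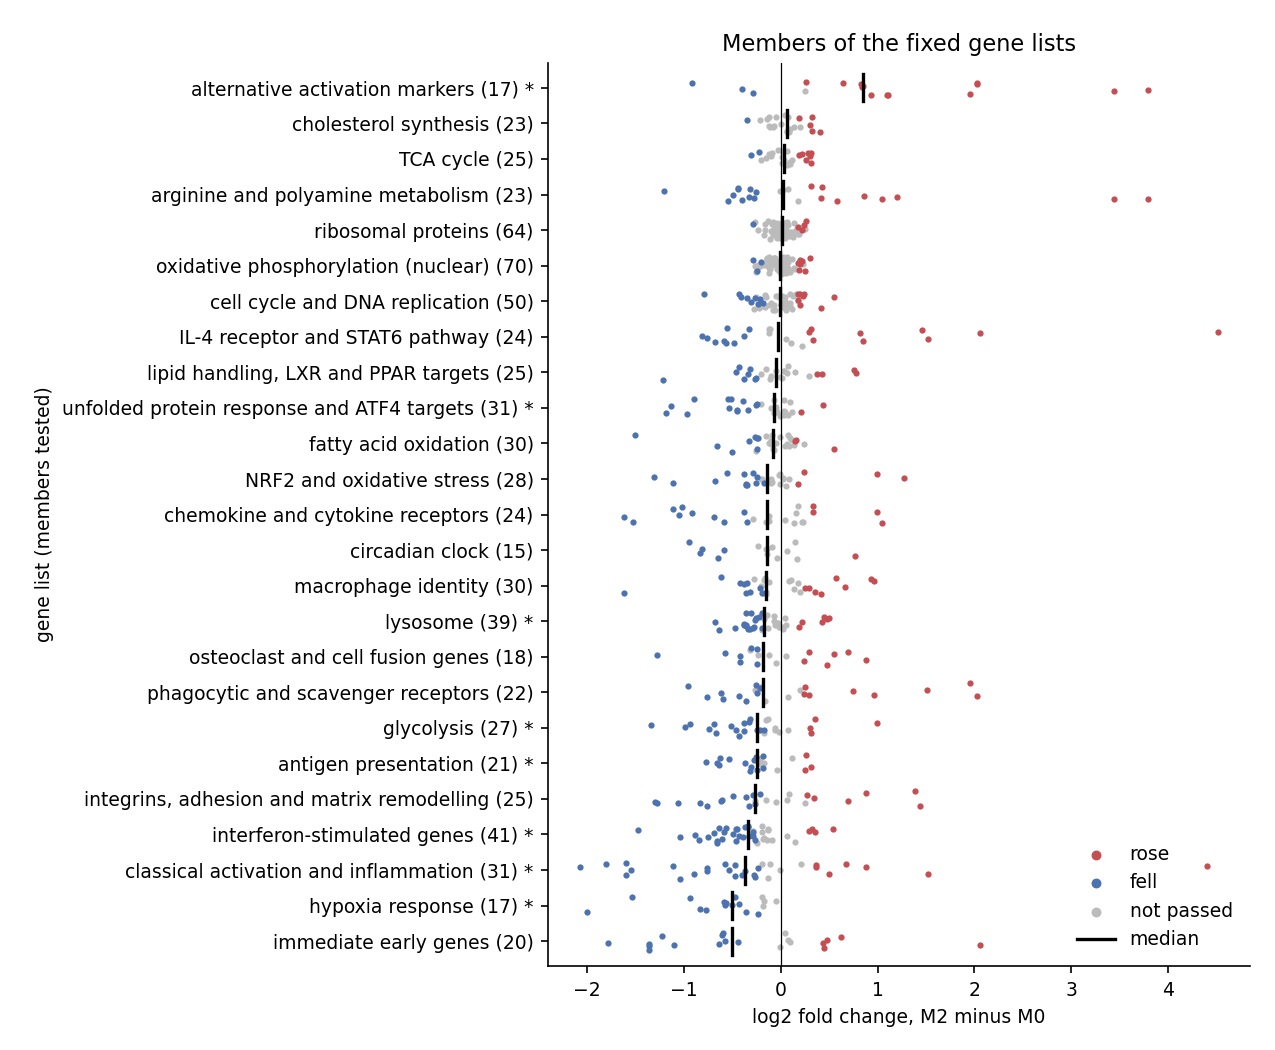
Points are the tested members of the 25 fixed lists with at least 5 of them, placed by log2 fold change (M2 minus M0); red members rose, blue members fell and grey members did not pass at an adjusted p under 0.05. Black bars are medians, which run from -0.51 to 0.85, numbers in brackets are tested members, and a star marks the 8 lists called by camera with the preset correlation.

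The other 17 lists did not pass as lists by camera with the preset correlation, although members changed in each. Of 25 TCA cycle genes 7 rose and 2 fell (7 and 2 adjusted over the list alone): Fh1 went from 221 to 275 TPM and Idh3a rose 1.22-fold, while Idh2 and Ogdh fell (camera adjusted p = 0.249). Of 70 nuclear genes of oxidative phosphorylation 8 rose and 3 fell (0 and 0 adjusted over the list alone), with Ndufs8 at 175 and 216 TPM and falls of Atp5d, Ndufv3 and Uqcrq; the median of -0.01 and the mean were below 0 and the camera direction was upward (adjusted p = 0.833). M0 replicates 1, 2 and 3 and then M2 replicates 1, 2 and 3 were left out in turn. In that order 3, 1, 1, 5, 7 and 7 of these genes rose and 0, 1, 0, 3, 0 and 15 fell. With the trend on gene length removed from every library, 9 rose and 11 fell. Fatty acid oxidation had 3 that rose and 8 that fell (1 and 6 adjusted over the list alone) among 30 tested (adjusted p = 0.518), with a 3.33-fold lower level of Ppard, a nuclear receptor, and rises of Acsl1, Acsl5 and Acat1. In cholesterol synthesis 5 rose and 1 fell (5 and 1 adjusted over the list alone) among 23 tested (adjusted p = 0.333); Cyp51 was 1.33-fold and Msmo1 1.24-fold higher, Idi1, Mvd and Hsd17b7 also rose, and Srebf2 fell. Mvd did not pass without M0 replicate 1, 2 or 3 (adjusted p = 0.0690, 0.0764 and 0.0528) or M2 replicate 1 (0.0664; 0.00467 to 0.0764 over 20 alternatives). Among 25 lipid handling genes 4 rose and 8 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.606), with the cholesterol exporter gene Abca1 2.42-fold lower and Angptl4 1.79-fold higher next to rises of Mylip, Apoe and Fabp4. In the same order of libraries left out, 2, 1, 1, 2, 1 and 5 fatty acid oxidation genes rose and 6, 4, 4, 7, 6 and 9 fell, 3, 4, 3, 3, 4 and 6 cholesterol synthesis genes rose and 1, 0, 0, 1, 1 and 3 fell, 1, 1, 1, 3, 2 and 3 TCA cycle genes fell and 8, 5, 7, 8, 9 and 8 lipid handling genes fell.

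Clock genes fell more often than they rose, with 1 that rose and 5 that fell (1 and 5 adjusted over the list alone) among 15 tested (camera adjusted p = 0.178). Nfil3 was the member that rose, and Bhlhe41, Rora, Csnk1e, Arntl and Per1 fell, Bhlhe41 from 31.9 to 17.8 TPM and Rora from 2.36 to 0.892 TPM. Cell cycle genes were split: of 50 tested 8 rose and 9 fell (7 and 8 adjusted over the list alone; camera adjusted p = 0.837), with Ccnd3 1.74-fold lower and Chek1 1.48-fold higher. Immediate early genes had a median of -0.51, with 5 that rose and 11 that fell (5 and 11 adjusted over the list alone) among 20 tested, and missed the threshold (adjusted p = 0.126, but 0.0485 downward with limma-voom without M2 replicate 3; 0.0485 to 0.619 over 21 camera alternatives). Dusp1 and Dusp6, phosphatases of MAP kinases, were 2.76-fold and 2.41-fold lower, and Myc, Atf3, Dusp2, Zfp36 and Dusp4 rose. NRF2 and oxidative stress genes had 4 that rose and 12 that fell (4 and 12 adjusted over the list alone) among 28 tested (adjusted p = 0.126, but 0.0210 downward without M2 replicate 3; 0.0210 to 0.481 over 21 camera alternatives). Within it, Gclm and Gclc, the subunits of the enzyme that begins glutathione synthesis, rose 2.44-fold and 2.03-fold with Sod2 and Taldo1, and Hmox1, heme oxygenase 1, fell from 115 to 52.8 TPM. Of 64 ribosomal protein genes 4 rose and 1 fell (0 and 0 adjusted over the list alone): Rpl5, Rpl7, Rps4x and Rpl10 rose by at most 1.21-fold, Rpl28 fell, and the list passed upward without M2 replicate 2 alone (adjusted p = 0.00556, against 0.375 with all libraries; 0.00556 to 0.951 over 21 camera alternatives). With M0 replicates 1, 2 and 3 and then M2 replicates 1, 2 and 3 left out in turn, 2, 0, 0, 4, 3 and 4 of these genes rose and 0, 0, 0, 0, 0 and 7 fell. In that order, 5, 2, 3, 5, 4 and 12 cell cycle genes rose and 9, 6, 5, 8, 7 and 9 fell, 2, 3, 3, 4, 4 and 4 NRF2 and oxidative stress genes rose and 1, 1, 1, 1, 1 and 2 clock genes rose. None of Rpl5, Rpl7, Rps4x and Rpl10 passed without M0 replicate 2 (adjusted p = 0.0782, 0.110, 0.0998 and 0.206 in that order) or 3 (adjusted p = 0.0940, 0.130, 0.109 and 0.120). Rpl5 had the lowest adjusted p of these (0.0298). It also did not pass without M0 replicate 1 (0.0687) or M2 replicate 2 (0.0577), within a range of 0.00634 to 0.0940 over 20 alternatives. With the trend on gene length removed from every library, Rpl10 did not pass (adjusted p = 0.103).

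Among 30 macrophage identity genes 8 rose and 9 fell (9 and 10 adjusted over the list alone; camera adjusted p = 0.861): Cx3cr1, the fractalkine receptor, was 3.57-fold lower, and Mertk, a receptor for apoptotic cells, rose from 9.67 to 19.8 TPM. Phagocytic and scavenger receptors had 8 that rose and 9 that fell (9 and 9 adjusted over the list alone) among 22 tested, with a median of -0.18, a mean of 0.15 and an upward test (adjusted p = 0.793). Havcr2, which encodes TIM-3, rose 3.33-fold and Clec4e, the lectin Mincle, fell from 160.3 to 82.0 TPM. Adhesion and matrix genes had 6 that rose and 13 that fell (7 and 13 adjusted over the list alone) among 25 tested (adjusted p = 0.272), with a rise of Mmp13 from 5.82 to 17.5 TPM, Tgfbi 2.69-fold higher and Mmp9 2.52-fold lower. Osteoclast and cell fusion genes had 6 that rose and 7 that fell (6 and 8 adjusted over the list alone) among 18 tested (adjusted p = 0.746), with Itgav and Cd44 1.92-fold and 1.63-fold higher. Of 24 chemokine and cytokine receptors 4 rose and 10 fell (4 and 10 adjusted over the list alone; camera adjusted p = 0.228): Cxcr4 was 3.20-fold and Il10ra 2.10-fold lower, and Il1rap, Tgfbr1, Ifngr2 and Il10rb rose. With M0 replicates 1, 2 and 3 and then M2 replicates 1, 2 and 3 left out in turn, 4, 4, 4, 4, 4 and 7 of the receptor genes rose.

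Of the markers of other cell types, 5 reached the filter. No marker of fibroblasts (12 in the table), of B and plasma cells (12) or of epithelial and endothelial cells (14) did so, and the highest mean among them was 0.730 TPM. Among T and NK cell markers, Cd28 and Lck were tested. Cd28 fell from 28.8 to 22.5 TPM (adjusted p = 0.0135; 0.0590 without M0 replicate 2; 5.80e-04 to 0.0590 over 20 alternatives), and Lck stood at 2.54 and 2.29 TPM (adjusted p = 0.390). S100a8, the tested neutrophil marker, stood at 5.29 and 4.81 TPM and did not pass. Of dendritic cell markers, Batf3 rose and Zbtb46 stood at 1.44 and 1.08 TPM without passing. Within these lists, adjusted over the list alone, Cd28 and Batf3 also passed.

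The authors' deposited table of their own comparison holds 5047 genes with an adjusted p under 0.05, 2607 of them higher in M2. Among 10685 genes in both tests, that table called 4686 and limma 4690. Of these, 4186 were called by both in one direction and 0 in opposite directions. In the authors' deposited table the log2 fold changes of Arg1 and Socs1 are 6.53 and 5.47, larger than those on log2(TPM + 1). Gene length tracked the differences between libraries of a group: over genes, the deviation of M2 replicate 3 from the other M2 libraries had a Spearman correlation of -0.61 with log2 length, against -0.42 to 0.56 for the other 5 libraries, and genes are not independent replicates.

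**Figure D4:**
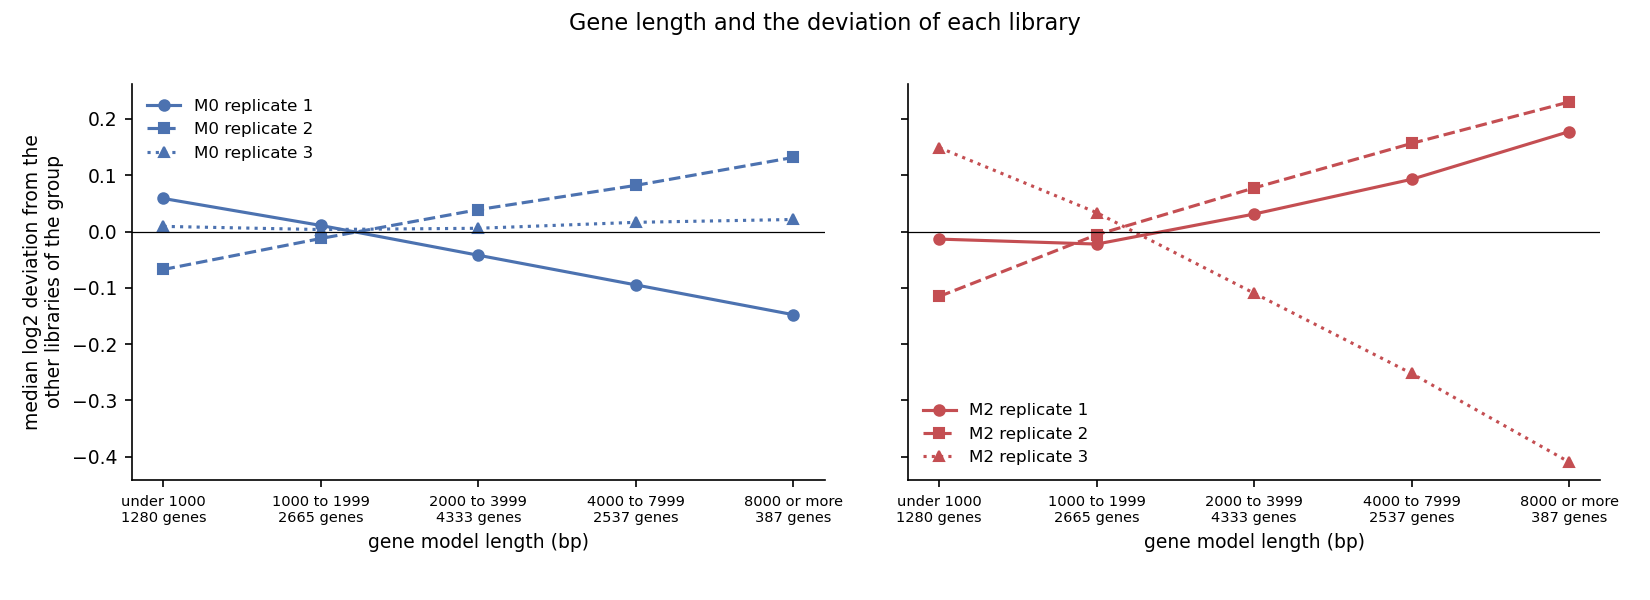
Lines give, for each library, the median log2 deviation from the other libraries of its group (vertical axis) over tested genes in 5 classes of gene model length in bp (horizontal axis), M0 on the left and M2 on the right. M2 replicate 3 runs from 0.15 in the 1280 shortest genes to -0.41 in the 387 longest, the steepest of the 6 libraries.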

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

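The search for the symbols of this part was chosen after the tables were seen. The authors' deposited table lists 64 gene symbols that the TPM table lacks even as older names, so these genes entered no comparison of the report. Of them, 6 have an adjusted p under 0.05 there, 5 higher and 1 lower in M2. That is a smaller share than in the whole of that table, where 5047 of 24421 genes do. These values lie outside the main measurement. By the log2 fold changes of the authors' deposited table, BC027231 (0.75), LOC100503496 (0.60), Gm17066 (0.41), BC030336 (0.27) and BC003331 (0.21) are higher in M2 and BC037034 is lower (-0.40). Groups of 3 libraries are too small for the rule on outlying samples used for this part, and with a single contrast no effect could be compared between contrasts. No biological explanation was tested.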

How the results depend on the processing

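Which choices were made before and after seeing the data is given with the processing; the scalings of TPM, the length correction, the authors' values, protein-coding genes alone, and limma-voom with the block, without M2 replicate 3 or with upper-quartile factors were chosen after. The count of 4899 changed genes stayed within 1.5 times under 20 alternatives, from 3556 to 6288, and 0 of the 4899 genes changed sign in any of those that tested them. The share that rose was 45.9%, and 41.8% to 51.2% over the alternatives. Leaving out 1 library gave 3556 to 5694 genes, 275 to 291 at 2-fold and 6 to 9 lists. The 275 genes at 2-fold became 472 with a pseudocount of 0.1, 477 with limma-voom, 469 with limma-voom and the block, 468 with limma-voom without M2 replicate 3, 495 with limma-voom and upper-quartile factors and 89 on the authors' log2-scale values; why was not tested. Of 116 named genes tested, 0 turned direction, 10 lost their call under at least 1 alternative and Spi1 gained it under 5.

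The 8 called lists became 5 on the authors' log2-scale values and 5 with limma-voom and upper-quartile factors, 15 with fry and 0 with an estimated correlation. With the estimated correlation the adjusted p was 0.283 for alternative activation and for the hypoxia response, 0.481 for classical activation, interferon-stimulated genes and antigen presentation, 0.593 for glycolysis, 0.619 for the unfolded protein response and 0.697 for the lysosome; correlations estimated from 6 libraries are imprecise. Under every other camera alternative the highest adjusted p was 1.55e-05 for alternative activation, 2.53e-06 for the hypoxia response, 4.75e-04 for interferon-stimulated genes, 0.00633 for glycolysis and 0.0335 for classical activation. Antigen presentation did not pass without the filter (0.162) or on the authors' values (0.0532), nor with limma-voom and upper-quartile factors (0.0528). The unfolded protein response did not pass with limma-voom (0.0964), limma-voom and the block (0.0947), limma-voom and upper-quartile factors (0.0882), median-ratio scaling (0.0958) or the authors' values (0.109), and ranged from 0.0113 to 0.0974 with 1 library left out. The lysosome did not pass with the stricter filter (0.0712), limma-voom (0.121), limma-voom and the block (0.106), limma-voom without M2 replicate 3 (0.0647), median-ratio (0.113) or upper-quartile scaling (0.0593), the authors' values (0.143), protein-coding genes alone (0.0766) or limma-voom and upper-quartile factors (0.112), and ranged from 0.0355 to 0.105 with 1 library left out. The cause of these losses was not tested. Of 374 values for the 17 lists that were not called, 12 passed.

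Replicate numbers are shared between the groups, but deviations from the group means of same-numbered libraries correlated at -0.03, 0.21 and 0.03 for numbers 1, 2 and 3. Not every library correlated best with its own number, so the numbers were not taken to pair the samples. With the replicate number as a block 4870 genes changed, 278 at 2-fold, and 8 lists were called, and 4645 of the 4899 genes stayed called. The alternatives set with the design for a count model were edgeR with RLE and upper-quartile factors, and the Wald test of DESeq2. They were tried on recovered reads in a separate trial and are not in the tables. In that trial, with edgeR, antigen presentation and the lysosome lost their calls, and the IL-4 receptor and STAT6, arginine and polyamine, immediate early and cytokine receptor lists gained one. In those fits the counts of changed genes and the directions of the called genes were like those of limma-voom. The gained list calls were not: with limma-voom on all libraries none of those lists passed. Depth limits low genes: Retnla and Chil3 had at most 5 reads over a group's libraries and were left out by the filter.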

Other observations

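The genes and lists of the first paragraphs, the removal of the length trend, the test of the re-analysis note, the comparison of receptor genes with other few-read genes and the splits for lists were chosen only after the result was seen. Ribosome biogenesis genes rose almost as a block: of 40 tested, 38 rose and 0 fell, with a median log2 fold change of 0.65 (95% bootstrap interval over genes 0.50 to 0.71). Bootstrap intervals in this part resample genes, which are not independent replicates, and do not measure the spread between libraries. Among polyamine genes, Odc1, which makes putrescine from ornithine, went from 46.6 to 69.9 TPM, Amd1 from 14.9 to 31.9 and Srm, spermidine synthase, from 68.1 to 124, and all 3 passed. Sat1 and Paox, of polyamine breakdown, fell with Smox, Sat1 from 56.3 to 41.4 TPM and Paox from 8.02 to 5.83. No list of synthesis or breakdown genes was tested. The fixed arginine and polyamine list had 9 that rose and 10 that fell among 23 tested, and did not pass (camera adjusted p = 0.333). Class II histocompatibility genes stayed below the filter: over the 3 libraries of each group, H2-Ab1 had 10 reads in M0 and 52 in M2, H2-Aa 0 and 26, and H2-Eb1 0 and 29.

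In a first hypothesis, the rise of Myc in M2 may go with a wider MYC programme, of which ribosome biogenesis genes are known targets. Their median of 0.65 lay above the bound of 0.1 set for it. The list, added after the comparison was seen, passed camera with the preset correlation (p = 6.69e-21) and with an estimated one (p = 0.00114), both unadjusted. Because the list was chosen with the comparison in view, neither its median nor its pass is an independent test of such a programme. The fixed lists of glycolysis (4 of 27 rose, 16 fell), cell cycle (8 of 50 rose, 9 fell) and ribosomal proteins (4 of 64 rose, 1 fell) did not rise as lists. The MYC programme stays a hypothesis, since MYC protein and binding were not measured. In a second hypothesis, the rises of Id1, Id3 and Skil may belong to a wider feedback of TGF-beta and BMP signalling. Of 7 tested SMAD target and feedback genes 5 rose and 2 fell, with a median of 0.48 (95% bootstrap interval over genes -0.19 to 1.07). The list passed with the preset correlation (p = 0.00953) and not with an estimated one (p = 0.0994), so 7 genes leave it open.

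M2 replicate 3 lay apart from the other M2 libraries: the SD of its deviations from them was 1.26 times the highest of the other 5 libraries. The deviations of M2 replicates 1 and 2 are taken from a mean that includes replicate 3, so their SDs are not independent of it. By the bound set in advance, a weaker response to IL-4 in M2 replicate 3 was argued against. The slope of its change on that of the other M2 libraries was 0.933 (SE 0.016, 285 genes), above 0.9. It lay between the slopes of M2 replicates 1 and 2 (0.923 and 0.967), but those have replicate 3 in their predictor. The SE is over genes, which are not independent replicates. Both changes are also taken from the same M0 mean, so the margin over 0.9 is uncertain. A trend with gene length could account for much of the distance of M2 replicate 3. With that trend removed from every library, the ratio of SDs fell to 1.11, between the bounds set in advance for and against the trend. Over genes, the fold change of M2 against M0 had a Spearman correlation of -0.11 with gene length, and 0.016 without that library. What produced the trend was not tested.

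Hypoxia response and glycolysis genes together, 42 genes, had a median log2 fold change of -0.34. A gene length trend between libraries was argued against as the whole cause. With that trend removed, the median was -0.34 (95% bootstrap interval over genes -0.48 to -0.22). A culture or library batch could also differ between the groups, because 3 of 3 M0 libraries carry the re-analysis note; batch and IL-4 cannot be told apart here. An effect of IL-4 itself stays open and untested.

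Genes with few reads (7043 genes with 1 to 30 reads over all libraries) were detected more often in M0 replicate 2 and M2 replicates 1 and 3 (4172, 4003 and 4014 genes) than in the other 3 libraries (2562, 3181 and 3006). Genomic DNA or another diffuse background stays open: reads in 1464 olfactory and vomeronasal receptor genes, which macrophages hardly transcribe, were 1.54 times as frequent in those libraries (exact 95% interval 1.34 to 1.79, counting error only), but most of these reads lie in few-read genes. Reads in the other few-read genes were 1.42 times as frequent, inside that interval, so the receptor genes show no more than the pattern itself. For cells of another type, the 71 few-read genes with the largest excess held 12.4% of it, against 11.1% on average and at most 11.9% in 100 random spreads of the reads. The excess was thus a little more concentrated than in these spreads, which hold counting error only, and short of the 25% set in advance for such cells. M0 replicate 2 and M2 replicates 1 and 3 also include more M2 libraries than the others do. Few-read genes that differ between the groups can therefore add to the concentration. The bound against such cells, 10%, lies below the random share, so the explanation stays open.

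The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05, the real split being 1 of 10 in the first of the counts that follow. The real split called 4899 genes and the highest of the other splits 0. At 2-fold the real split called 275 genes and the highest other 0, again with 1 split as large. Every other split mixes M0 and M2 on each side, so the group difference widens its spread and makes calls unlikely. The counts of 0 therefore do not test what separates the groups. For lists, the real split called 8 and the highest other 9, and 3 of the 10 splits called at least 8. The mixed splits keep part of the group difference, which can move whole lists. The list counts are therefore not a rate of chance calls either.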
